A study of Homo sapiens with 6 samples.

How the data were processed

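RNA from human retinal microvascular endothelial cells was compared 48 h after transfection with control siRNA (3 libraries) or ADAM10 siRNA (3 libraries). Per the labels' protocols, RNA was extracted with TRIZOL and libraries were made with the Lexogen QuantSeq 3' mRNA-seq FWD kit, which counts fragments near the 3' end of polyadenylated transcripts, so that counts do not scale with transcript length. The authors deposited raw read counts per gene symbol in 1 table for all 6 libraries. Per the submitters' processing notes, STAR 2.7.5a, HTSeq 0.6.1, edgeR and the build hg38 were used, with no role or order given. The gene annotation, the strand setting and the handling of reads with more than 1 position are not given in the sources used here, so genes with close copies or overlapping neighbours are less certain. The table had 27470 gene rows, of which 27469 held counts and 1 was blank in every library and was left out. Its 6 empty trailing columns were ignored, and 10264 rows were at 0 in all libraries. No row of unassigned reads was listed.

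Total counts ran from 10114648 to 11157896 per library. At this depth the median tested gene had a count of 254 in a library. Counting error is part of the spread between replicates. The labels name no molecular identifiers, so copies made by PCR may be counted more than once.

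Groups were taken from the treatment label of each sample. Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr (defaults, minimum count 10 and minimum total count 15), libraries were scaled by TMM, and ADAM10 siRNA was compared with control siRNA by the quasi-likelihood test (glmQLFit and glmQLFTest, two-sided, no covariate). Benjamini-Hochberg adjusted p under 0.05 was the threshold. CPM values use TMM-scaled library sizes over the 12279 genes tested, which held at least 99.88% of the counts of each library. Fold changes are given as log2 values with their SE or as ratios, and means with the SD of 3 libraries. The test, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined.

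Named genes were ADAM10; then, among genes past the threshold with a mean of at least 5 CPM and CPM values that did not overlap between groups, the 12 with the largest rise and the 12 with the largest fall, leaving out genes without a symbol and XIST and Y-linked genes; then up to 4 members of each gene list with the smallest adjusted p among those past the threshold, or up to 2 with the smallest p where none passed. Other list members past the threshold were added where a small count would otherwise stay unnamed, and are marked as named after their values were seen. A few of the genes chosen this way are not reported here.

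A total of 31 gene lists was fixed. They covered Notch targets and arterial genes; Notch ligands, receptors and processing; ADAM sheddases and regulators; ADAM10 substrates; tip cell genes; VEGF and angiopoietin signalling; endothelial identity; endothelial junction and barrier; venous genes; NF-kB inflammatory genes; interferon response; cell cycle; p53 targets; unfolded protein and integrated stress response; hypoxia and glycolysis. They also covered cholesterol synthesis and uptake; extracellular matrix and basement membrane; TGF-beta and BMP targets; endothelial-mesenchymal transition; YAP and TEAD targets; flow-responsive KLF genes; coagulation and fibrinolysis; Wnt and beta-catenin targets; markers of pericytes and smooth muscle, fibroblasts, lymphatic endothelium, retinal pigment epithelium with neurons and glia, leukocytes and epithelium; and RNA quality lists of mitochondrial transcripts and of nuclear-retained and histone transcripts. Of 680 list entries 665 matched the table, 9 of them by an older symbol. Lists with at least 3 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), with Benjamini-Hochberg adjustment over 26 lists, and again with an estimated correlation. The pericyte and smooth muscle list had 1 tested member, the fibroblast list 0, the retinal pigment epithelium, neuron and glia list 2, the leukocyte list 2 and the mitochondrial list 0. With the preset correlation 10 lists passed, 3 up and 7 down; with an estimated correlation 1 passed, the Notch targets and arterial genes. The rotation test fry, which asks whether members move one way without comparing them with other genes, passed for 9 lists. These included the NF-kB list (fry adjusted p = 0.00991), but not the sheddase list (fry adjusted p = 0.0807) or the coagulation list (fry adjusted p = 0.233). The median, mean and camera direction did not share a sign for the Notch ligand and receptor list (median 0.01, mean -0.04, down), ADAM10 substrates (0.11, -0.03, down), endothelial identity (0.00, -0.04, up), junction and barrier genes (0.03, -0.03, down) and the nuclear-retained and histone list (-0.11, -0.02, up).

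The planned share of mitochondrial counts was replaced, because none of the 13 protein-coding mitochondrial symbols of the list occurs in the table; the summed share of the symbols RNR1 and RNR2 is given instead. These symbols are not defined in the table.

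For words in 3' UTRs, GENCODE 29 annotation on GRCh38 was used, which may differ from the authors' annotation. The longest annotated 3' UTR was searched for 11267 tested genes (91.8%), ADAM10 left out. For each 7-base word in at least 50 genes, fold changes of genes with and without the word were compared by a two-sided rank-sum z in 10 strata of UTR length, and 100 permutations of fold changes within strata gave the most extreme z expected by chance. A second run used strata of length and of AU content together. Coordinates of named genes come from the same annotation.

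Scripts were tested on simulated data. In simulated counts for this comparison with 220 changed genes among 12046, the test recovered 44.8% of 1.5-fold, 68.7% of 2-fold and 98.4% of 4-fold changes, and 8.12% of calls were false. With no simulated change it called 0 genes. A planted 7-base word ranked 1 among all words.

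Alternatives were RLE, upper quartile and library size scaling; no count filter; a mean of at least 5 CPM; DESeq2 1.42.0; limma-voom; the replicate number as a block; an adjusted p under 0.01; an absolute log2 fold change of at least 1; estimated list correlation; words of 6 and 8 bases; all UTR sequence; protein-coding genes as denominator of the RNR share; and each library left out in turn. Bias-adjusted quasi-likelihood deviances, offsets for trends over 3' UTR composition and length, and lists without word carriers were added after the data were seen. Python 3.11.15 with numpy, scipy and pandas was used for the word search and matplotlib 3.10.9 for plots.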

Results

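Gene expression was measured in human retinal microvascular endothelial cells (HRMVECs), which line the small vessels of the retina, 48 h after transfection with an siRNA against ADAM10 or a control siRNA. A small interfering RNA (siRNA) pairs with a target mRNA and lowers its level. ADAM10 encodes a membrane-bound metalloprotease that cuts the extracellular part off many surface proteins, among them Notch receptors and cadherins. Each group held 3 libraries made with a kit that reads the 3' ends of polyadenylated transcripts. Total counts were 11083136, 10114648 and 11157896 in control siRNA replicates 1, 2 and 3, and 10612656, 10146996 and 10897767 in ADAM10 siRNA replicates 1, 2 and 3. Between 14260 and 14774 genes had at least 1 count in a library. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

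The targeted gene was examined in every library first. ADAM10 (chromosome 15, positions 58588807 to 58749978, minus strand, GRCh38) had 679, 716 and 842 counts in the control siRNA libraries and 247, 185 and 263 counts in the ADAM10 siRNA libraries. Its mean level fell from 68.9 ± 7.20 to 21.98 ± 2.88 CPM (counts scaled to a common library total; SD, n = 3 per group). The log2 fold change was -1.65 ± 0.13 (SE; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 2.5e-08). The remaining level was 31.9% of control, with a 95% interval of 26.4 to 38.7%. All 3 ADAM10 siRNA libraries lay below all 3 control libraries, for which a two-sided exact permutation test gives p = 0.1, the smallest value that 3 against 3 libraries allow.

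The comparison asked which transcripts differ in retinal endothelial cells when ADAM10 mRNA is reduced. Notch target and arterial genes, tip cell genes, cell cycle genes, cholesterol synthesis genes and targets of TGF-beta, BMP and YAP were lower as groups in the ADAM10 siRNA libraries, and venous genes and p53 targets were higher. These are calls of camera with a preset correlation; with an estimated correlation the Notch target and arterial list kept its call (camera adjusted p = 0.028), and the other 7 lists named here did not (camera adjusted p from 0.0727 to 0.132). Among named genes with a mean of at least 5 CPM, the acid phosphatase gene ACP5 rose most, and the kinase gene UHMK1 and the sulfotransferase gene CHST1 fell most. Of 12279 genes tested, 405 rose and 503 fell, 908 in all (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). In an alternative chosen after the data were seen, trends over the AU content and length of 3' UTRs were removed. Under it 377 rose and 377 fell, so the excess of lowered genes did not hold there. These trends were fitted in each library, so their removal also takes out any effect of the siRNA that follows these features. Changes of at least 2-fold were seen in 30 raised and 86 lowered genes. CPM values of the groups did not overlap for 902 of the 908 genes. Over all tested genes 25.7% had no overlap, where chance gives 10%. The count of changed genes was 501 without control siRNA replicate 1, 472 without control siRNA replicate 3 and 568 without ADAM10 siRNA replicate 3. ADAM10 siRNA replicate 2 stood apart from its replicates: the chi-square per degree of freedom between its counts and theirs was 10.3 and 11.2, against 5.45 between the other pair, and without it 947 genes changed.

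**Figure D1:**
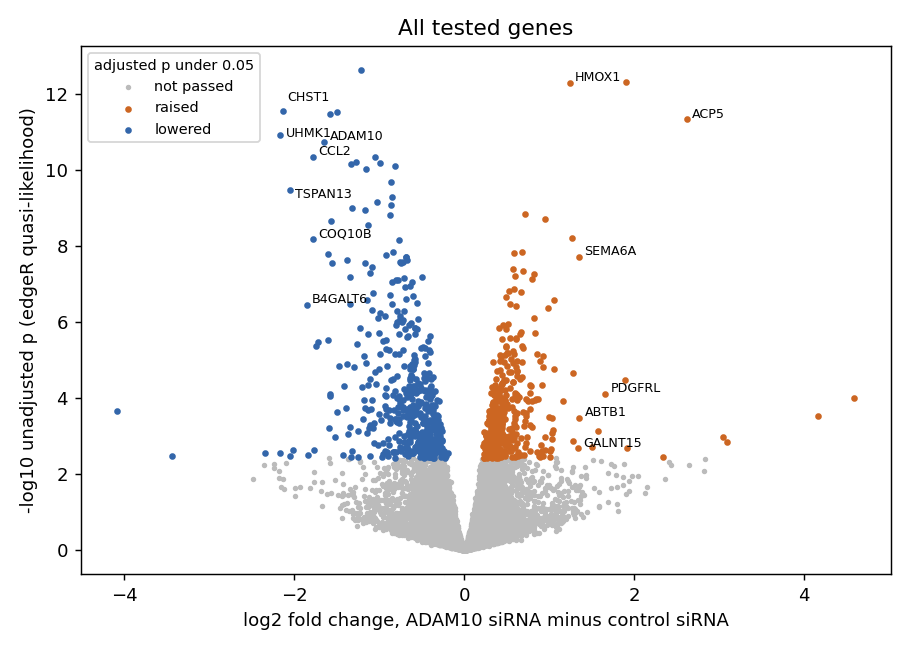
Log2 fold change (ADAM10 siRNA minus control siRNA, horizontal axis) against -log10 of the unadjusted p of edgeR's quasi-likelihood test (vertical axis) for all 12279 tested genes; orange points are the 405 raised and blue points the 503 lowered genes at an adjusted p under 0.05, grey points the rest. ADAM10, at -1.65, lies among the lowered genes, and ACP5, at 2.62, carries the largest rise among the labelled genes.

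Genes switched on by Notch signalling and genes of arterial endothelium fell together. Of 13 tested members 6 fell and none rose, and 9 fell when adjusted over the list alone. The median log2 fold change was -1.13 (camera adjusted p = 4.2e-14; adjusted p = 0.028 with an estimated correlation). HES1, a transcriptional repressor and direct Notch target, fell from 134 ± 10.1 to 60.9 ± 12.9 CPM (SD, n = 3 per group). NRARP, a feedback inhibitor of Notch signalling, fell from 28.3 ± 3.12 to 9.62 ± 1.79 CPM. EFNB2, which encodes the arterial ligand ephrin-B2, fell from 45.8 ± 4.72 to 21.8 ± 2.61 CPM, and the chemokine receptor gene CXCR4 from 14.5 ± 1.62 to 4.75 ± 1.34 CPM. The adjusted p of these 4 genes ranged from 1.17e-06 to 0.000306 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). UNC5B and HES4, named after their values were seen, made up the 6, with log2 fold changes of -1.38 and -1.11. In contrast, none of 25 tested genes for Notch ligands, receptors and processing enzymes passed the test, over all genes or adjusted over the list alone, and their median was 0.01 (camera adjusted p = 0.943). The ligand gene JAG2 stood at -0.50 ± 0.17 (log2 fold change ± SE). It passed without ADAM10 siRNA replicate 1 (adjusted p = 0.0366), without a count filter (adjusted p = 0.018) and once trends over 3' UTR composition were removed (log2 fold change -0.595, adjusted p = 0.0328; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

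Venous genes moved the other way. Of 9 tested members 3 rose and none fell, and adjusted over the list alone 4 rose and 1 fell. The median log2 fold change was 0.53 (camera adjusted p = 6.18e-05; adjusted p = 0.0727 with an estimated correlation). NR2F2, the transcription factor COUP-TFII that sets venous identity, rose from 1157 ± 92.4 to 1734 ± 74.6 CPM (SD, n = 3 per group), or 1.498-fold. The gene for the venous ephrin receptor EPHB4 rose 1.51-fold, from 242.0 ± 17.2 to 364 ± 23.6 CPM, and that for the co-receptor NRP2 rose 1.45-fold, from 264 ± 19.7 to 382 ± 10.3 CPM (SD, n = 3 per group). The 3 adjusted p values lay between 5.37e-06 and 5.4e-05 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

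**Figure D2:**
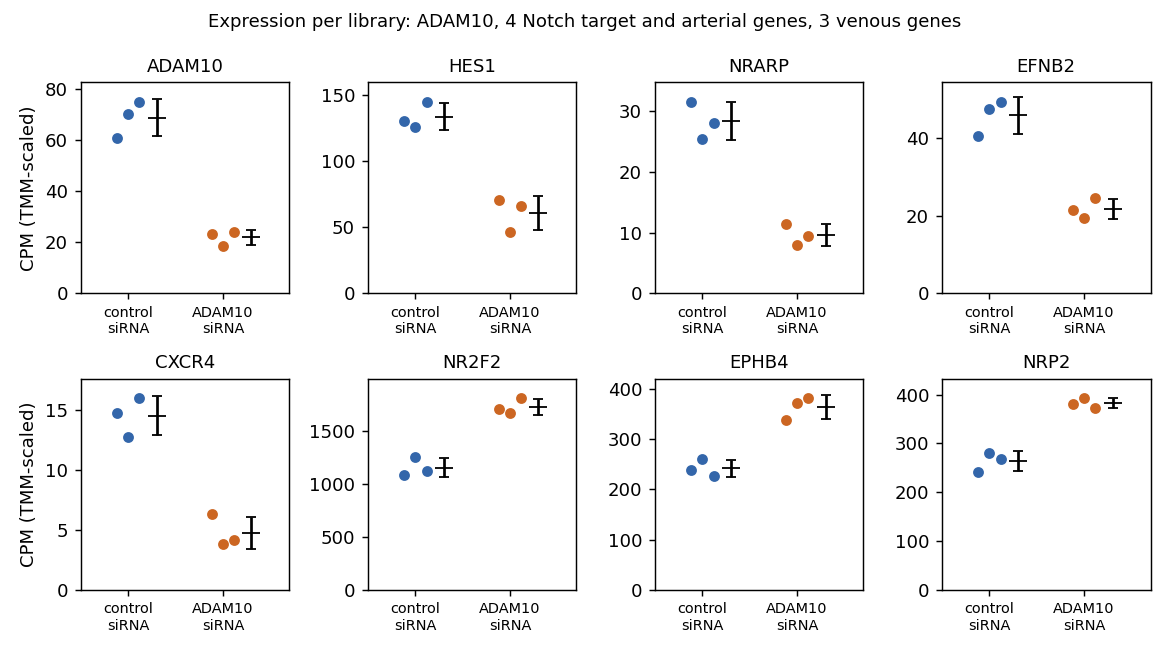
CPM (vertical axes, linear, from 0) of ADAM10, of 4 Notch target and arterial genes and of 3 venous genes in each control siRNA library (blue) and ADAM10 siRNA library (orange); black marks show the mean and SD of 3 libraries. The groups do not overlap in any panel: ADAM10 goes from 68.9 to 21.98 CPM and HES1 from 134 to 60.9 CPM on average, while NR2F2 goes from 1157 to 1734 CPM.

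Tip cell genes, which mark the leading cells of a vessel sprout, were lower. Of 19 tested members 6 fell and 1 rose, and adjusted over the list alone 10 fell and 1 rose. The median log2 fold change was -0.29 (camera adjusted p = 1.37e-07; adjusted p = 0.132 with an estimated correlation). ESM1, which encodes the proteoglycan endocan, fell 1.81-fold, from 215 ± 8.37 to 119 ± 11.2 CPM. CD34 fell 2.51-fold, the angiopoietin gene ANGPT2 1.72-fold and the growth factor gene PDGFB 1.69-fold, and the basement membrane gene NID1 rose 1.42-fold. NID1 lost its call without control siRNA replicate 3 (adjusted p = 0.0584, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). PGF and APLN, named after their values were seen, completed the 6 tip cell genes that fell, at -0.77 and -0.24, and APLN lost its call in 4 of the 6 fits without 1 library (adjusted p up to 0.175, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). In the wider list of VEGF and angiopoietin signalling 2 of 25 tested members rose, NRP2 and SEMA3F, and 1 fell, ANGPT2, with 4 and 1 adjusted over the list alone (camera adjusted p = 0.401). SEMA3F, at 0.36 ± 0.10 (log2 fold change ± SE), lost its call without any 1 of 5 libraries, with adjusted p from 0.078 to 0.153 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

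General endothelial genes did not move as a group. Among 27 tested endothelial identity genes 5 rose and 4 fell, and 9 rose and 6 fell adjusted over the list alone (median 0.00, camera adjusted p = 0.926). The adhesion gene CDH5, encoding VE-cadherin, fell 1.79-fold, from 368 ± 15.4 to 205 ± 37.1 CPM (SD, n = 3 per group). EMCN, encoding endomucin, rose 1.34-fold and VWF, encoding von Willebrand factor, rose 1.28-fold. VWF lost its call once trends over 3' UTR composition were removed (log2 fold change 0.24, adjusted p = 0.0734, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). MMRN2, ECSCR and FLI1 also rose, by 0.37, 0.29 and 0.26 on the log2 scale, and CLEC14A and EGFL7 fell by 0.36 and 0.29; these 5 were named after their values were seen. Without 1 library, FLI1 lost its call in 5, EGFL7 in 4, CLEC14A in 2 and ECSCR in 1 of the 6 fits, with adjusted p up to 0.181, 0.223, 0.114 and 0.104 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of 23 tested junction and barrier genes 1 rose and 2 fell, and 2 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.926). The connexin gene GJA1 fell 1.42-fold, the transporter gene ABCG2 fell 1.76-fold and CD99L2 rose 1.39-fold. ABCG2 lost its call without any 1 of the 6 libraries (adjusted p from 0.08 to 0.199) and CD99L2 without control siRNA replicate 2 (adjusted p = 0.065; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

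The list of other sheddases and their regulators was higher by camera with the preset correlation. It mixes membrane and secreted protease genes with genes for partners and inhibitors, and the rotation test fry did not pass for it (fry adjusted p = 0.0807). Of 24 tested members 7 rose and 1 fell, and 9 rose and 3 fell adjusted over the list alone. The median was 0.14 (camera adjusted p = 0.00807; adjusted p = 0.315 with an estimated correlation and 0.0819 without control siRNA replicate 3). The metalloprotease gene ADAM15 rose 1.33-fold, from 854 ± 5.79 to 1136 ± 46.2 CPM, and TSPAN5, which encodes a tetraspanin partner of ADAM10, rose 1.41-fold, from 207 ± 5.51 to 291 ± 18.5 CPM. ADAMTS9, a secreted protease gene, rose 1.59-fold. TIMP1, which rose 1.35-fold, encodes an inhibitor of metalloproteases, so the members that rose included at least 1 protease inhibitor. ADAM19, named after its values were seen, was the 1 that fell, at -0.62, and lost its call in 3 of the 6 fits without 1 library (adjusted p up to 0.094, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Among 29 tested genes for proteins that ADAM10 cuts, 3 rose and 4 fell, and 6 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.944). These included CDH5, EFNB2 and the adhesion gene ALCAM, which fell by 0.59 on the log2 scale, and EPHB4, which rose. SDC4, at -0.67, and APP and NECTIN1, at 0.30 and 0.48, were the others past the threshold, named after their values were seen. They lost their calls in 1, 3 and 4 of the 6 fits without 1 library, with adjusted p up to 0.0924, 0.0607 and 0.192 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

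Genes of the cell cycle were slightly lower. Of 43 tested members 5 fell and none rose, and 6 fell adjusted over the list alone. The median was -0.16 (camera adjusted p = 0.000681; adjusted p = 0.0727 with an estimated correlation). PCNA, the sliding clamp of DNA replication, fell 1.73-fold, from 140.4 ± 16.2 to 81.3 ± 14.3 CPM. CENPE, CDK1 and NDC80 fell by 0.33, 0.44 and 0.40 on the log2 scale, and TOP2A, named after its values were seen, by 0.23. CENPE lost its call in 3, CDK1 in 4, NDC80 in 4 and TOP2A in 5 of the 6 fits without 1 library, with adjusted p up to 0.145, 0.112, 0.186 and 0.198 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). A change of scaling alone also ended the TOP2A call in this test, with adjusted p = 0.0519 for RLE and 0.0563 for upper quartile scaling. Once trends over 3' UTR composition were removed these 4 lost their calls, with log2 fold changes of -0.158, -0.295, -0.246 and -0.108 and adjusted p from 0.126 to 0.489 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), while PCNA and the list kept theirs. Targets of p53 were higher: of 26 tested members 6 rose and 2 fell, and 11 rose and 2 fell adjusted over the list alone. Their median was 0.20 (camera adjusted p = 0.000189; adjusted p = 0.0727 with an estimated correlation). The stress-induced SESN2 rose 1.58-fold, the ferredoxin reductase gene FDXR 1.49-fold, the cell cycle inhibitor gene CDKN1A 1.30-fold and TP53I3 1.33-fold. MDM2 and TNFRSF10B, named after their values were seen, fell by 0.38 and 0.37, and TNFRSF10B lost its call in 5 of the 6 fits without 1 library (adjusted p up to 0.164, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

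The cholesterol synthesis and uptake list was lower, with 3 of 26 tested members falling and none rising, and 4 falling adjusted over the list alone. The list also holds the fatty acid genes FADS1, FADS2, SCD and FASN, and FADS2 was among those that fell. The median was -0.16 (camera adjusted p = 0.00479; adjusted p = 0.132 with an estimated correlation). HMGCS1, an early enzyme of the mevalonate pathway, fell 1.57-fold, from 47.5 ± 4.18 to 30.1 ± 2.499 CPM. MSMO1 and FADS2 fell by 0.37 and 0.31, and each lost its call in 5 of the 6 fits without 1 library, with adjusted p up to 0.111 and 0.26 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The unfolded protein and integrated stress response list showed no net direction, with 2 of 28 tested members rising and 3 falling, and 2 and 4 adjusted over the list alone (camera adjusted p = 0.259). Its strongest member was SLC7A11, the cystine transporter gene, which fell 2.82-fold, from 153 ± 9.27 to 54.1 ± 9.58 CPM. MANF fell 1.37-fold, the serine synthesis gene PHGDH, named after its values were seen, fell by 0.76 on the log2 scale, and SEL1L and PDIA4 rose 1.41-fold and 1.36-fold. PDIA4 lost its call without control siRNA replicate 2 (adjusted p = 0.0596) and without ADAM10 siRNA replicate 1 (adjusted p = 0.0604), and PHGDH in 4 of the 6 fits without 1 library (adjusted p up to 0.185; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). In the hypoxia and glycolysis list 1 of 25 tested members passed, over all genes and adjusted over the list alone (camera adjusted p = 0.7). This was PGK1, which fell by 0.28 and lost its call in 5 of the 6 fits without 1 library (adjusted p up to 0.124, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

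Targets of TGF-beta and BMP signalling were lower: of 16 tested members 5 fell and 1 rose, and 6 fell and 1 rose adjusted over the list alone. The median was -0.22 (camera adjusted p = 0.000221; adjusted p = 0.132 with an estimated correlation). HES1, also a Notch target, was among them. The matrix protein gene CTGF fell 1.69-fold, from 792 ± 54.8 to 469.8 ± 74.6 CPM, and SKIL, a repressor in this pathway, fell 1.99-fold. INHBA and ID1, named after their values were seen, fell by 0.75 on the log2 scale and rose by 0.50. Targets of YAP and TEAD overlapped with these through CTGF. Of 18 tested members 5 fell and none rose, and 7 fell adjusted over the list alone (median -0.16, camera adjusted p = 9.89e-05; adjusted p = 0.132 with an estimated correlation). The ectonucleotidase gene NT5E fell 1.89-fold, CYR61 1.61-fold and the kinase gene STK38L 2.15-fold, and ANKRD1, named after its values were seen, fell by 0.32. CYR61 missed the threshold in DESeq2 (adjusted p = 0.0844), and STK38L without control siRNA replicate 1 or 3 (adjusted p = 0.0517 and 0.0627 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). ANKRD1 lost its call without control siRNA replicate 2 and without ADAM10 siRNA replicate 3 (adjusted p = 0.0806 and 0.0695, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

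Coagulation and fibrinolysis genes were lower by camera with the preset correlation, with 5 of 20 tested members falling and 2 rising, and 7 and 3 adjusted over the list alone. The rotation test fry did not pass for the list (fry adjusted p = 0.233). The median was -0.12 (camera adjusted p = 0.0188; adjusted p = 0.499 with an estimated correlation). The call was lost without control siRNA replicate 1 (camera adjusted p = 0.114) and without ADAM10 siRNA replicate 2 (camera adjusted p = 0.227). NT5E fell and VWF rose in this list too, and the cyclooxygenase gene PTGS1 rose 1.38-fold, a call lost in 4 of the 6 fits without 1 library. F2RL1, PLAU and TFPI, named after their values were seen, fell by 1.25, 0.76 and 0.26 and lost their calls in 5, 5 and 3 of these fits.

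Matrix and basement membrane genes went both ways, with 4 of 27 tested members rising and 2 falling, and 6 and 5 adjusted over the list alone (camera adjusted p = 0.926). The collagen cross-linking enzyme gene LOX fell 2.96-fold, from 46.3 ± 5.08 to 15.6 ± 3.46 CPM, and the thrombospondin gene THBS1 fell 1.46-fold, from 1142 ± 26.5 to 781 ± 112 CPM. NID1 rose, and the laminin gene LAMC1 rose 1.22-fold, which was lost in 5 of the 6 fits without 1 library. LAMB2 and COL5A1, named after their values were seen, rose by 0.40 and 0.33 and lost their calls in 5 of these fits. In the endothelial-mesenchymal transition list TPM1 fell 1.32-fold and MMP2 rose 1.27-fold among 10 tested members, with the same 1 and 1 adjusted over the list alone (camera adjusted p = 0.926). MMP2 lost its call in 4 of the 6 fits without 1 library. Among 9 tested flow-responsive genes only PODXL passed, falling 1.54-fold, and 2 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.672). PODXL lost its call without control siRNA replicate 3 (adjusted p = 0.0895, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). None of 12 tested Wnt and beta-catenin targets passed, over all genes or adjusted over the list alone (camera adjusted p = 0.7). The nearest were FZD4, at 0.25 ± 0.11, and SOX17, at -0.27 ± 0.13 (log2 fold change ± SE), and FZD4 passed without ADAM10 siRNA replicate 2 (adjusted p = 0.00106, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

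Inflammatory genes split. Of 23 tested NF-kB genes 3 fell and 1 rose, both over all genes and adjusted over the list alone, with a median of -0.20 (camera adjusted p = 0.0525; adjusted p = 0.188 with an estimated correlation, and camera adjusted p = 0.0365 without ADAM10 siRNA replicate 3). The chemokine gene CCL2 fell 3.43-fold, from 80.1 ± 9.71 to 23.3 ± 5.76 CPM, and CXCL2 fell 2.17-fold, from 11.5 ± 2.29 to 5.28 ± 1.53 CPM. IL1A fell from 2.13 ± 0.854 to 0.412 ± 0.0414 CPM, close to the detection limit, and the adhesion receptor gene ICAM1 rose 1.52-fold. CXCL2 and ICAM1 lost their calls in 3 and IL1A in all 6 fits without 1 library, with adjusted p up to 0.0905, 0.11 and 0.239 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). With all 6 libraries IL1A also lost its call in limma-voom (adjusted p = 0.0812). In edgeR's quasi-likelihood test it did so without a count filter (adjusted p = 0.0784) and with the replicate block (adjusted p = 0.0592). Of 35 tested interferon-response genes 5 rose and 1 fell, over all genes and adjusted over the list alone (median 0.07, camera adjusted p = 0.298). The antiviral OAS3 rose 1.43-fold, BST2 and IFI6 rose 1.20-fold and 1.17-fold, and the exonuclease gene ISG20 fell 1.57-fold. BST2, IFI6 and ISG20 each lost the call in 4 of the 6 fits without 1 library. MX1 and IFI44L, named after their values were seen, rose by 0.31 and 0.26 and lost their calls in 5 and 4 of these fits.

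Single calls in several lists ended once trends over 3' UTR composition were removed, which can also take out effects of the siRNA. Among genes that had risen, the log2 fold change went from 0.36 to 0.259 for SEMA3F, from 0.26 to 0.165 for BST2, from 0.35 to 0.291 for MMP2, from 0.48 to 0.382 for NECTIN1, from 0.31 to 0.252 for MX1, from 0.33 to 0.279 for COL5A1 and from 0.40 to 0.257 for LAMB2. Among genes that had fallen it went from -0.82 to -0.721 for ABCG2, from -2.34 to -2.232 for IL1A, from -0.28 to -0.239 for PGK1, from -0.37 to -0.295 for MSMO1, from -0.32 to -0.226 for ANKRD1, from -1.25 to -1.203 for F2RL1 and from -0.26 to -0.144 for TFPI. The adjusted p of these genes ranged from 0.0581 to 0.248 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

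**Figure D3:**
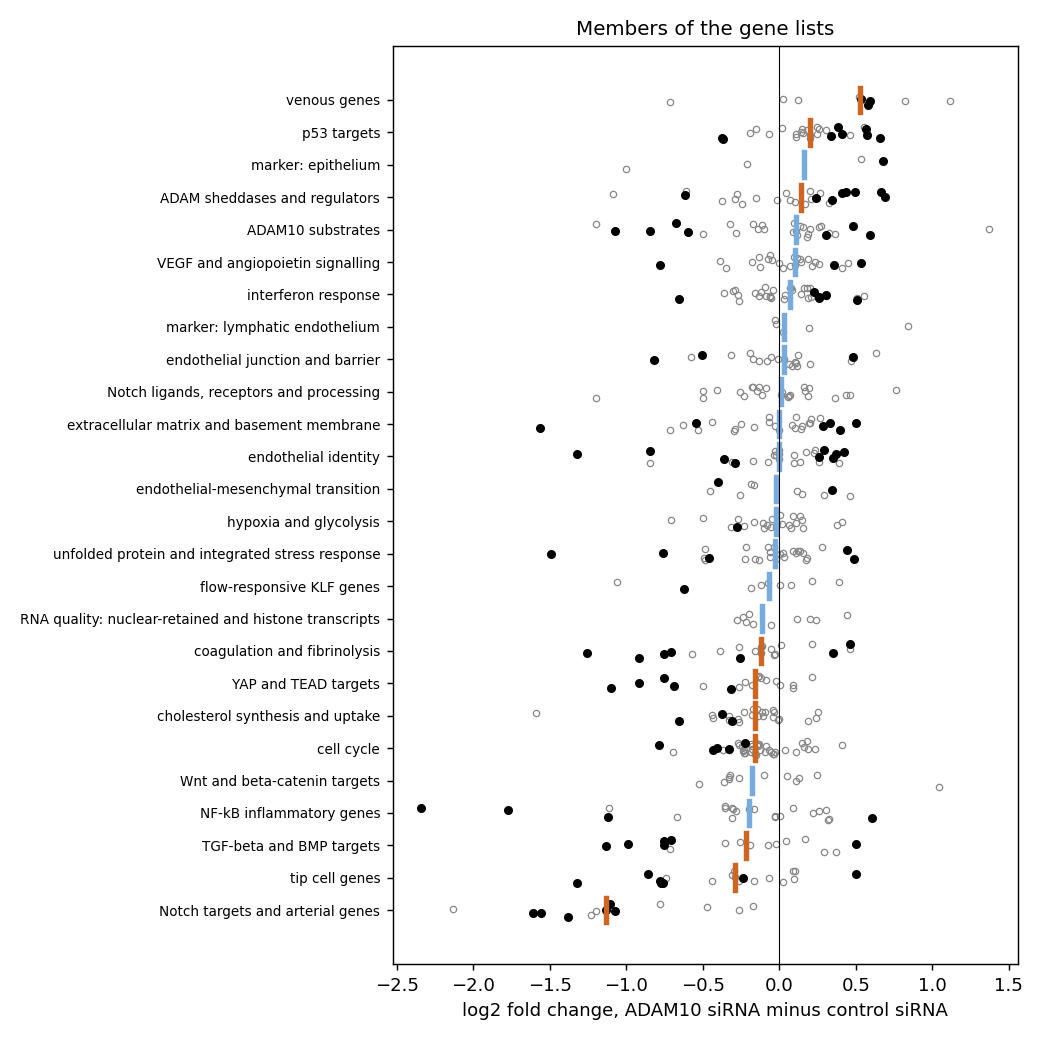
Log2 fold change (ADAM10 siRNA minus control siRNA, horizontal axis) of each tested member of the 26 tested gene lists (vertical axis, ordered by median); filled points passed an adjusted p under 0.05 over all genes and open points did not, with vertical jitter for legibility. Bars mark list medians, orange where the camera adjusted p with the preset correlation was under 0.05 and blue elsewhere; the Notch target list lies lowest, at -1.13, and the venous list highest, at 0.53.

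The largest changes outside these lists covered several functions. ACP5, encoding tartrate-resistant acid phosphatase (chromosome 19, 11574660 to 11579008), rose 6.14-fold, from 5.04 ± 0.882 to 30.9 ± 2.08 CPM. The heme oxygenase gene HMOX1 (chromosome 22, 35380361 to 35394214) rose 2.36-fold, from 88.1 ± 4.78 to 208 ± 10.6 CPM. The semaphorin gene SEMA6A, the neurotensin receptor gene NTSR1, the protease gene ADAMTS18, the gamma-glutamyltransferase gene GGT5, BAALC, PDGFRL, ABTB1, GALNT15 and the metallothionein gene MT1F rose between 2.09-fold and 3.16-fold. ABTB1 lost its call without control siRNA replicate 3 (adjusted p = 0.059), GALNT15 in 4 and MT1F in 5 of the 6 fits without 1 library (adjusted p up to 0.211 and 0.103, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). UHMK1 (chromosome 1, 162497251 to 162529629) fell 4.48-fold, from 54.5 ± 5.83 to 12.1 ± 3.21 CPM, and CHST1 (chromosome 11, 45648877 to 45665622) fell 4.40-fold, from 44.8 ± 4.35 to 10.2 ± 0.666 CPM. The tetraspanin gene TSPAN13 fell 4.16-fold, the glycosyltransferase gene B4GALT6 3.61-fold and the coenzyme Q gene COQ10B 3.43-fold. L3HYPDH, TRIM16, ITGB3BP, the translation factor gene EIF5A2 and PGM2L1 fell between 2.98-fold and 3.36-fold. MT1F and TRIM16 have close sequence copies in the genome, so their counts could be split among copies and are less certain.

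Few markers of other cell types passed the count filter, and among those that did KRT19 rose and SYT1 fell. RGS5, a pericyte marker, was the only tested gene of the pericyte and smooth muscle list and stood at 1372 ± 54.6 CPM in control and 1350.5 ± 33.2 CPM in ADAM10 siRNA libraries. The other members of that list had at most 11 counts over all 6 libraries (MYH11), and PDGFRB and CSPG4 had 1 each. RGS5 thus stood alone among these markers. No fibroblast marker passed the count filter. Of the leukocyte markers only CD14 and CD68 were tested, at 0.720 and 2.45 CPM in control libraries, and neither passed. Of the retinal pigment epithelium, neuron and glia markers 2 were tested, and the synaptotagmin gene SYT1 fell 2.30-fold, from 25.5 ± 1.03 to 11.1 ± 5.70 CPM. The lymphatic genes PROX1, at 0.84 ± 0.27, and LYVE1, at 0.19 ± 0.10 (log2 fold change ± SE), did not pass. Without ADAM10 siRNA replicate 2 both passed (adjusted p = 0.0181 and 0.00857, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and the camera adjusted p of the lymphatic list went from 0.401 to 0.0187; PROX1 also passed without control siRNA replicate 2 (adjusted p = 0.043), with composition trends removed (adjusted p = 0.0328), without a count filter (adjusted p = 0.0305), with bias-adjusted deviances (adjusted p = 0.0486) and in DESeq2 (adjusted p = 0.0455). None of its 5 tested members passed over all genes, and 1 rose adjusted over the list alone. Among 4 tested epithelial markers KRT19 rose 1.60-fold, from 155 ± 6.82 to 249 ± 14.2 CPM, and 1 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.43). None of 10 tested nuclear-retained and histone transcripts passed, and 2 rose adjusted over the list alone (camera adjusted p = 0.944); MEG3, at 0.44 ± 0.16, passed without control siRNA replicate 2 (adjusted p = 0.0173) and without a count filter (adjusted p = 0.00116), and H1F0 stood at 0.24 ± 0.09 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The genes listed as RNR1 and RNR2 took 4.57 ± 0.0658% of counts in control and 4.79 ± 0.411% in ADAM10 siRNA libraries (SD, n = 3 per group; two-sided exact permutation p = 0.4, where 0.1 is the smallest possible).

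Lowered genes carried a short word in their 3' untranslated regions (3' UTRs) more often than other genes. Over 16199 7-base words, GTAGATA marked the lowered genes most strongly, with a rank-sum z of -16.69 stratified by UTR length, against -5.1 for the most extreme of 100 permutations. In these strata 1513 words passed this bound, among them AATATTT (-15.01), made of A and T alone, and 2067 passed the bound for raised genes. The bound is therefore not particular to GTAGATA. In strata of length and AU content together 5 words passed a bound of -4.66, and GTAGATA led them at -12.41. The median log2 fold change was -0.16 for the 1016 genes with the word in the longest annotated 3' UTR and 0.01 for the other 10251. Of the lowered genes with a searched 3' UTR, 163 of 484 carried it (33.7%), against 838 of 10395 genes not called (8.06%) and 15 of 388 raised genes (3.87%). The word was chosen on the fold changes of the same genes, so these shares describe it and are no further test. Neither the shares nor the medians were adjusted for the length or AU content of 3' UTRs. Of the 12 leading lowered genes 7 carried it: UHMK1, TSPAN13, B4GALT6, COQ10B, ITGB3BP, EIF5A2 and PGM2L1. None of the 12 leading raised genes carried it. In the gene lists CD34, CDH5, PCNA, SLC7A11, PGK1, LOX, THBS1, SKIL, NT5E, STK38L, SYT1 and TOP2A carried it among the named genes that fell, as did MDM2 and ADAM19, and ADAMTS9, NR2F2 and IFI44L carried it among those that rose. None of the 13 tested Notch target and arterial genes carried it. ADAM10 itself held the word at 2 places in the 3' UTR of its longest transcript.

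**Figure D4:**
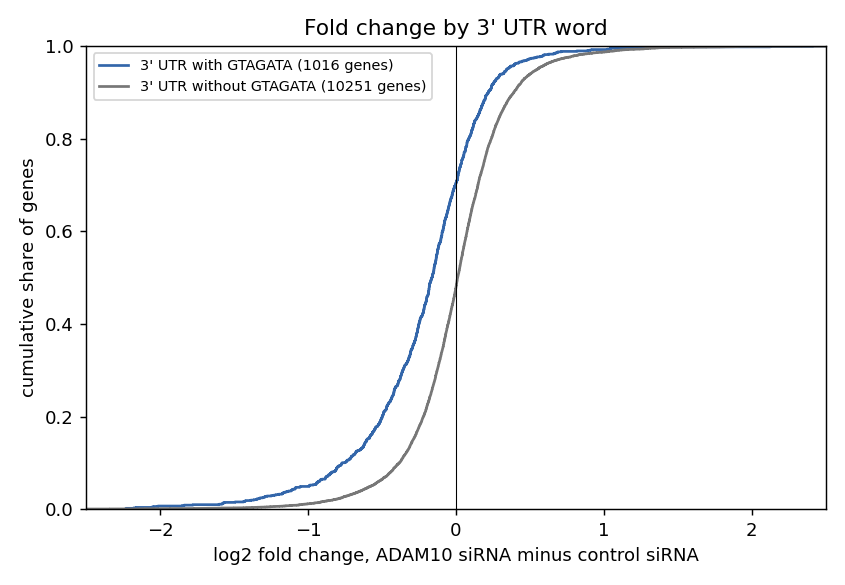
Cumulative share of genes (vertical axis) by log2 fold change, ADAM10 siRNA minus control siRNA (horizontal axis, with the few genes beyond its ends not drawn), for 1016 genes with the word GTAGATA in the longest annotated 3' UTR (blue) and 10251 genes without it (grey). The curve of genes with the word lies to the left, with a median of -0.16 against 0.01. The curves are not adjusted for the length or AU content of 3' UTRs.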

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

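The bias-adjusted deviances, the offsets for 3' UTR composition, the counts without carriers of the word GTAGATA and the word search in strata of AU content were chosen after the results were seen. The ADAM10 fall kept its direction and its call under every alternative, with log2 fold changes from -1.73 to -1.54 when 1 library was left out. Of 908 changed genes, 896 kept the call with RLE, 893 with upper quartile, 849 with library size scaling, 897 without a count filter, 886 at a mean of at least 5 CPM, 891 in DESeq2, 866 in limma-voom, 906 with bias-adjusted deviances and 599 with composition offsets, and none of the 908 passed with the opposite sign in these fits. Totals under these alternatives ran from 754 genes with composition offsets to 1145 without a count filter. DESeq2 gave no adjusted p for 1429 genes.

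At an adjusted p under 0.01, 431 genes changed (172 up, 259 down), and 116 (30 up, 86 down) at an absolute log2 fold change of at least 1; both are stricter. Leaving out 1 library gave 472 to 947 changed, 195 to 442 raised and 277 to 505 lowered genes, lowest without control siRNA replicate 3 and highest without ADAM10 siRNA replicate 2. The counts were also lower without control siRNA replicate 1 (501) and ADAM10 siRNA replicate 3 (568), and 266 genes rose without control siRNA replicate 2; fewer libraries give the test less power, but any other cause was not tested. Leaving out carriers of the word and genes with no annotated 3' UTR left 321 lowered genes, by construction. Genes with related words such as TAGATAA were not left out.

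The replicate number of the labels was also fitted as a replicate block, which gave 1177 changed genes (535 up, 642 down), 904 of them among the 908, and 11 gene lists past the threshold. With the block JAG2 and MEG3 also passed (adjusted p = 0.0311 and 0.00359, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Whether the numbers pair the libraries stays open. Deviations of same-numbered libraries from group means correlated across 9896 genes at 0.09, 0.11 and 0.00. Other pairs lay at -0.12 to 0.06 (genes are not independent replicates).

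Between 9 and 11 lists passed under the alternatives with the preset correlation, and 1 list passed with an estimated correlation, the Notch targets and arterial genes. The sheddase list lost its call without a count filter (camera adjusted p = 0.0587), and the coagulation list without carriers of the word (camera adjusted p = 0.139). The NF-kB list gained one with upper quartile scaling (camera adjusted p = 0.0491), with the replicate block (camera adjusted p = 0.0395) and without carriers (camera adjusted p = 0.0384). The cause of these was not tested.

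Lists whose median changed sign did not pass with all 6 libraries, and the cause was not tested. The median of Notch ligands, receptors and processing was -0.003 with library size scaling, -0.034 without a count filter and -0.025 with composition offsets. That of endothelial identity was -0.001 with RLE, -0.011 with library size scaling, -0.002 in limma-voom and -0.001 with the replicate block. The median of matrix and basement membrane genes was 0.005 with upper quartile scaling, 0.046 without a count filter, 0.084 at a mean of at least 5 CPM, 0.001 with the replicate block, 0.027 with composition offsets and 0.092 without carriers of the word. For endothelial-mesenchymal transition it was 0.151 without a count filter and 0.112 with composition offsets. Leaving out 1 library gave medians of -0.048 to 0.03 for Notch ligands, receptors and processing, -0.027 to 0.035 for junction and barrier genes, -0.05 to 0.006 for the unfolded protein and integrated stress response, -0.104 to 0.009 for hypoxia and glycolysis, -0.104 to 0.047 for matrix genes and -0.038 to 0.202 for endothelial-mesenchymal transition. The ranges were -0.088 to 0.019 for flow-responsive genes, -0.017 to 0.255 for lymphatic markers, -0.056 to 0.245 for epithelial markers and -0.148 to 0.053 for nuclear-retained and histone transcripts.

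Of 127 genes chosen by the naming rule or added, 68 kept direction and call under every alternative. Over 2025 such values, 1787 kept both, 213 lost the call, 21 gained one and 4 changed sign. Fits without 1 library made up most of the losses, 39 of them without control siRNA replicate 3, and composition offsets 20. The sign changes were in genes that did not pass: RGS5 stood at 0.096 with composition offsets and at -0.046 to 0.009 without 1 library, CD14 at -0.16 to 0.727 and CD68 at -0.102 to 0.485 without 1 library. CD14 and CD68 have few counts, so depth limits them.

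The difference in the RNR1 and RNR2 share was 0.223 percentage points, 0.252 with protein-coding genes as denominator and 0.072 to 0.457 without 1 library. The z of the leading word was -16.8 over all UTR sequence, -18.24 for 6 bases (TAGATA), -13.0 for 8 bases (GTAGATAA) and -12.41 in strata of AU content. GTAGATAA occurs in 0 of 7 protein-coding ADAM10 transcripts. Simulated 1.5-fold changes were recovered in 44.8% of genes, so other genes can hold changes of that size.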

Other observations

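Tests chosen after the results were seen were those of scaling and of the endothelial share for the Notch target list, those of depth and of 3' UTR features for ADAM10 siRNA replicate 2, the word search among genes that lack the word GTAGATA, the offsets for 3' UTR composition and the word search in strata of AU content. Across 11267 genes, which are not independent replicates, the log2 fold change correlated with the AU content of the 3' UTR (Spearman rho -0.29) and hardly with its length (rho -0.04). Each library's deviation from the mean of all 6 correlated with AU content at 0.22, 0.21 and 0.20 in control siRNA replicates 1, 2 and 3 and at -0.11, -0.32 and -0.15 in ADAM10 siRNA replicates 1, 2 and 3 (9471 genes).

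With 10 splits of the 6 libraries no share under 0.05 can be reached. The real split was the 1 of 10 with as many changed genes, 908 against at most 0 in the others, and the 1 of 10 with as many lists past the threshold, 10 against at most 6.

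Genes that fell carried the word GTAGATA in their 3' UTRs more often than others, which may mark pairing of the ADAM10 siRNA with transcripts other than ADAM10 through its seed, the first bases of its guide strand. The z was -16.69, against -5.1 in the most extreme of 100 permutations, and ADAM10 holds the word in 1 of 7 protein-coding transcripts. Of all 7-base words 45.4% occur there, so that presence says little, and the siRNA sequences are not given in the labels. The leading 8-base word GTAGATAA and the shifted 7-base word TAGATAA occur in 0 of these 7 transcripts. The requirement that the leading word occur in ADAM10 was set for 7-base words and was met by GTAGATA. Absence of the longer and the shifted word decides nothing on pairing. Both end in an A beyond the end of GTAGATA, and whether the siRNA pairs with that base is not known. Base composition alone is argued against, since the z stayed at -12.41 against -4.66 in strata of AU content, where the other words past that bound were TAGATAA (-8.87), AGATAAA (-5.25) and AGATAAT (-5.07), which overlap it when shifted, and TAAATAA (-5.44), which does not. The word occurred in 163 of 484 searched lowered genes. Among genes that lack it, in the same strata, TAAATAA (-5.27) passed the bound of -4.82. TAGATAA, which shares the bases TAGATA with the word, lay at that bound (-4.82) and had 878 carriers. Pairing through the shared bases cannot be told apart there from composition left within strata. Genes that lack GTAGATA can thus still hold a related site. For the raised genes, release from a control siRNA cannot be told apart from composition either: the leading word CCCTCCC reached 16.54 in strata of length, but 4.48 against 5.34 with AU content added.

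The fall of the Notch target and arterial list may follow from reduced cleavage of Notch receptors by ADAM10, a hypothesis that these RNA counts do not test and that a measurement of cleaved Notch receptor protein would. Pairing at GTAGATA in the longest annotated 3' UTR is argued against, since the 13 members all lack it there and have a median of -1.13. Members that lack the word are thus the whole list. Related words such as TAGATAA, and other parts of the transcripts, were not examined in these members. Scaling was examined through the median of all tested genes, which stayed within 0.012 of 0 under 3 other scalings. RLE and upper quartile scaling hold most genes near 0 by design, so they decide little. With library size scaling alone the median was -0.012, which argues against the choice of scaling as the source of -1.13. A shift shared by all genes cannot be seen with any of them. Base composition is argued against by a camera adjusted p of 3.96e-16 with composition offsets. A lower share of endothelial cells is argued against by the endothelial identity list, whose median was 0.001 (SD 0.42 over members). Pairing at related words and indirect effects of other genes lowered by the siRNA stay open, since the labels name no other ADAM10 siRNA.

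ADAM10 siRNA replicate 2 lay at 40.4 on the first principal component (33% of variance), against 10.3 and 11.2 for its replicates. Control siRNA replicate 2, of like depth, differed from its replicates by at most 6.87 in chi-square per degree of freedom, against 10.3 and 11.2 here. That measure is scaled to counting error and does not rise as depth falls, so it could not have spoken for low depth. No conclusion on depth is drawn from it. Trends over the AU content and length of 3' UTRs are argued against as the whole cause, since the SD of its deviations across genes was 0.332 before and 0.326 after their removal, against at most 0.264 after removal in the other 5 libraries. A stronger response to the siRNA cannot be told apart from a difference in the cells or library: its median relative change was 0.886, but the same measure gave 0.814 and 0.86 for replicates 1 and 3, so a ratio under 1 does not speak against it. No biological explanation was tested beyond this, since the labels give none for single libraries.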
